A study of Arabidopsis thaliana with 24 samples.

How the data were processed

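The series holds 24 libraries of polyadenylated RNA from whole Arabidopsis thaliana seedlings of 14 days, made with a kit that tags the 3′ end of transcripts. Groups were taken from the labels: 4 growth settings (lab LD, LD+FR+TEMP, natural 2013 and natural 2014) at ZT4 and ZT16, with 3 replicates each. The deposited count files hold whole-number read counts per transcript model for 48359 models of 27655 genes. Per the submitters' processing notes, the authors used bcl2fastq 2.17.1.14, Trimmomatic 0.36, Bowtie2 and edgeR with the TAIR10 build. The notes state neither the order nor the settings, and they do not name the counting step. The deposited normalized table holds signal values that equal the deposited counts times 1 factor per library, which was tested on the values. Its columns differ in their sums, so it is not plain CPM. It lists 26793 models, and a threshold of 2 CPM in at least 3 libraries passes 26794, of which 1 is not in the table. No column of these files was left unused (0 columns).

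Counts of transcript models were summed to genes, because reads shared by models of 1 gene appeared to be assigned at random. Over 831 genes whose 2 models held about equal counts, of 1749 examined, the squared difference of the counts divided by their sum had a median of 0.993, where random assignment gives 1, and 1.91% of the pairs were identical. Gene names came from a reference table of assembly TAIR10.1, used for names alone, in which 27445 loci matched and 210 organelle loci did not. The strand used in counting is not stated, so a gene and an antisense or overlapping partner were not separated. Counts of near-identical copies are also uncertain, because the notes do not state how reads that match several copies were counted. Among them are SAUR19 to SAUR24, the LHCB1, LHCB2 and RBCS genes, KIN1 and KIN2, VSP1 and VSP2, the AOC genes and the small heat shock proteins.

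Comparisons were run in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr with the groups (minimum count 10, minimum total count 15), which left 18797. Library sizes were scaled by TMM, and a quasi-likelihood model with 1 mean for each of the 8 groups and no block was fitted to all 24 libraries. The common dispersion was 0.0143, a biological coefficient of variation of 0.119. Each contrast was tested with edgeR's quasi-likelihood F test, adjusted after Benjamini and Hochberg over all genes tested, with a threshold of 0.05. The standard error was the size of the log2 fold change divided by the square root of F. Log2 CPM for the principal components used a prior count of 2. The 14 contrasts were LD+FR+TEMP against lab LD, natural LD (the mean of both years) against lab LD and against LD+FR+TEMP, and natural 2014 against natural 2013, each at ZT4 and ZT16, ZT16 against ZT4 in each setting, and the interaction of time with LD+FR+TEMP and with natural LD, each against lab LD.

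A total of 24 gene lists with 364 members were written from general knowledge of the species, and 8 members whose name and locus could not be matched were left out. They covered flowering promoters and repressors, morning and evening clock genes, shade avoidance, auxin, gibberellin, cold, heat shock, flavonoids, UV-B and high light, salicylic acid, jasmonate and ethylene, abscisic acid and drought, glucosinolates, iron, phosphate, photosynthesis, sugar starvation, senescence, cell division, and markers of root, floral organs and seed storage. Each list was tested with camera, which compares its genes with all others, at a preset correlation of 0.01, in 14 contrasts. The seed storage markers had 2 genes tested and no list test, so 23 lists gave 322 tests. The same tests were repeated with an estimated correlation and with fry, which asks whether the genes of a list move on balance in 1 direction and compares them with no other genes. The samples, the 14 contrasts, their tests, the lists and the rule for naming genes were fixed before the data were examined. So were the alternatives, except for thinned libraries and the dropped library. The interaction of year and time of day and the closer tests of root markers and morning clock genes were also chosen after seeing the data.

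That rule named FT, TSF, CO, SOC1, GI, FKF1, CDF1, FLC and PIF4 in any contrast. From each list it named up to 3 members higher and 3 lower with the smallest adjusted p among those past the threshold whose libraries did not overlap, and the first tested member that did not pass. Of each contrast it also named the 5 genes higher and 5 lower with the largest change and a mean of at least 5 CPM in the higher group. Overlap was not asked for interactions. Where the compared group held 0 to 3 counts of a gene, no fitted fold change was printed. A floor of 3 counts over the group was used for bounds, and bounds cover counting error only. With members at 0 in 1 group set to that bound, the 22 medians of tested lists that held such members moved by at most 1.24. The 4 medians of the 2 seed storage markers, which had no list test, moved by 1.36 to 3.2. The afternoon and evening clock genes in natural 2014 moved from 2.86 to 1.62.

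Likeness of 2 changes against the same lab LD libraries was described by correlation, covariance, shared sign and shared calls, beside simulated unchanged groups. Alternatives were relative log expression factors, DESeq2 1.42.0, limma-trend on log2 of the deposited signal plus 1, no filter, a mean of at least 5 CPM, a log2 fold change of at least 1 beside the threshold, the compared groups alone, 1 outdoor year alone, the replicate number as a block, no organelle genes, each library left out in turn, libraries thinned to the smallest, and 1 library dropped. Tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 and plots with matplotlib 3.10.9.

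The tests were tested on simulated data, drawn from the means and library sizes of the real genes with 67, 67 and 66 genes changed 1.5-fold, 2-fold and 4-fold. For LD+FR+TEMP against lab LD at ZT4 (18578 genes) edgeR recovered 53.7%, 77.6% and 98.5% of these, and 3.8% of its calls were false. At ZT16 (18585 genes) it recovered 50.7%, 80.6% and 92.4%, with 3.9% false. For natural LD against lab LD it recovered 61.2%, 82.1% and 97.0% at ZT4 (18556 genes, 3.6% false) and 62.7%, 85.1% and 98.5% at ZT16 (18583 genes, 3.0% false). For natural LD against LD+FR+TEMP it recovered 67.2%, 92.5% and 95.5% at ZT4 (18580 genes, 6.6% false) and 59.7%, 86.6% and 98.5% at ZT16 (18572 genes, 7.4% false). For ZT16 against ZT4 in natural 2014, the comparison of 2 groups with the lowest 1.5-fold share, the shares were 34.3%, 80.6% and 95.5% (18595 genes, 6.0% false). For the interaction with LD+FR+TEMP they were 7.5%, 56.7% and 83.3% (18590 genes, 5.8% false), and with natural LD 19.4%, 68.7% and 95.5% (18573 genes, 6.2% false). With totals of 6543615 to 16089156 counts per library, changes of 1.5-fold were thus missed more often than larger ones. In LD+FR+TEMP against lab LD at ZT4, DESeq2 recovered 49.3%, 73.1% and 98.5% (18797 genes, 7.5% false) and limma-trend 35.8%, 74.6% and 98.5% (3.5% false). A simulated list of 15 changed genes passed camera in both contrasts tried, and 0 of 50 unchanged lists did. Genes were drawn independently of each other and the unchanged lists at random. The simulation therefore cannot show how camera behaves with lists of correlated genes. It also gave all groups the same spread at a given mean. Correlations between real replicates at ZT4 ran from 0.9748 to 0.9765 in lab LD and from 0.9872 to 0.9901 in LD+FR+TEMP. The shares recovered and false may therefore not hold where the spread of the compared groups differs.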

Results

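Polyadenylated RNA was counted in whole Arabidopsis thaliana seedlings, grown on soil to an age of 14 days, with a method that reads a tag near the 3′ end of each transcript. The 24 libraries formed 8 groups of 3 replicates, from 4 growth settings sampled at zeitgeber time 4 (ZT4, morning) and 16 (ZT16, evening). Lab LD was the standard indoor long day. LD+FR+TEMP was an indoor long day in which a 730 nm diode set the ratio of red to far-red light to 1 and the temperature followed a daily programme between 15.8 and 22.8 °C, with 17.9 °C at ZT4. Natural LD was an outdoor cage in June 2013 or July 2014, shaded by garden fabric that left the red to far-red ratio unchanged.

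At ZT4 the total counts per library ran from 6841485 to 9775572 in natural 2013, 7175100 to 8268281 in natural 2014, 14256033 to 15176090 in LD+FR+TEMP and 12069812 to 16089156 in lab LD. At ZT16 the ranges were 6543615 to 7821026, 9681843 to 10711582, 14056348 to 16001512 and 14132231 to 14756759 in the same order. Every outdoor library was therefore shallower than every indoor one. Genes encoded in the organelles held 0.49% to 0.61% of the counts as group means, with standard deviations of 0.02 to 0.11. The 10 most abundant genes of each library held 9.13% to 12.83% as group means, with standard deviations of 0.13 to 1.15. The first principal component of log2 CPM (counts-per-million) took 39.0% of the variance and placed all ZT4 libraries above 0 and all ZT16 libraries below 0. The second took 16.6% and placed the natural 2014 libraries and the natural 2013 ZT16 libraries above 20 and the indoor libraries below -10. Natural 2014 ZT4 replicate 1 lay farthest out on both.

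**Figure D1:**
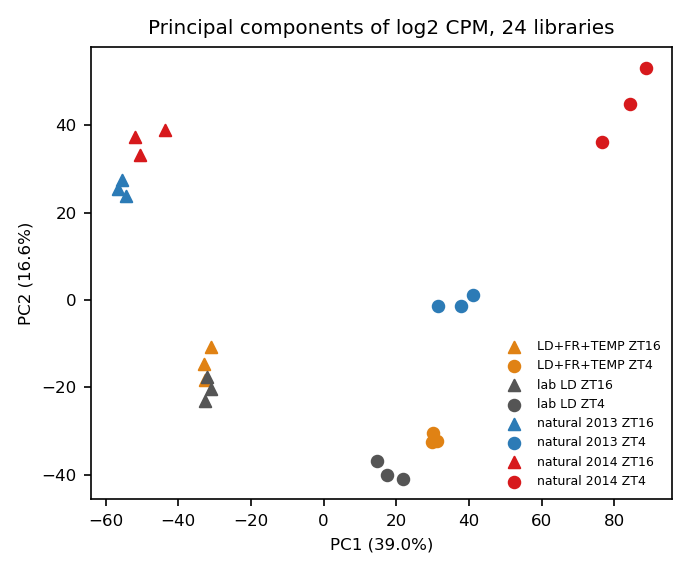
Each point is 1 of 24 libraries, placed on the first (39.0% of the variance) and second (16.6%) principal component of log2 CPM, with circles for ZT4 and triangles for ZT16. The ZT4 libraries lie to the right and the ZT16 libraries to the left, and natural 2014 ZT4 lies apart from natural 2013 ZT4.

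All comparisons came from 1 edgeR quasi-likelihood fit of the 24 libraries, in which 18797 of 27655 genes were tested. Errors of log2 fold changes are standard errors (SE), errors of CPM are standard deviations (SD) with n = 3 per group, and adjusted p-values follow Benjamini and Hochberg. Apart from FT, TSF, CO, SOC1, GI, FKF1, CDF1, FLC and PIF4, a gene named as changed between groups had no overlap between the libraries of the compared groups. Counts of list members are given over all genes tested, followed by the count adjusted over the list alone. The labels do not say whether replicates came from separate plantings, so the p-values measure the spread between these samples only.

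The series asks how flowering is timed under natural long days, and FT (AT1G65480), the gene of the mobile flowering signal florigen, was examined first. In lab LD, FT was low in the morning (1.84 ± 0.197 CPM) and higher in the evening (10.7 ± 0.465 CPM). In LD+FR+TEMP, it stood at 6.96 ± 1.87 CPM at ZT4 and 7.4 ± 0.949 CPM at ZT16. Outdoors, the morning mean was the higher one, past the threshold in 2014 and not in 2013, with 20 ± 3.98 CPM at ZT4 and 15.6 ± 1.32 CPM at ZT16 in 2013, and 25.2 ± 7.29 CPM and 11.9 ± 3.79 CPM in 2014. FT at ZT4 was thus 3.77-fold higher in LD+FR+TEMP than in lab LD (log2 fold change 1.92 ± 0.28, adjusted p = 2.57e-05) and 12.2-fold higher in natural LD than in lab LD (3.60 ± 0.24, adjusted p = 1.42e-11). Adjusted over the list alone (32 members of both flowering lists), these p-values were 8.48e-06 and 1.42e-12. At ZT16, FT differed from lab LD by less than the test could call in LD+FR+TEMP (-0.54 ± 0.21, adjusted p = 0.164) and in natural LD (0.34 ± 0.18, adjusted p = 0.133). Without natural 2014 ZT16 replicate 2, the natural LD value passed (0.46). FT in natural LD exceeded that in LD+FR+TEMP at ZT4 (1.69 ± 0.19, adjusted p = 4.08e-07) and at ZT16 (0.88 ± 0.19, adjusted p = 0.000895).

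**Figure D2:**
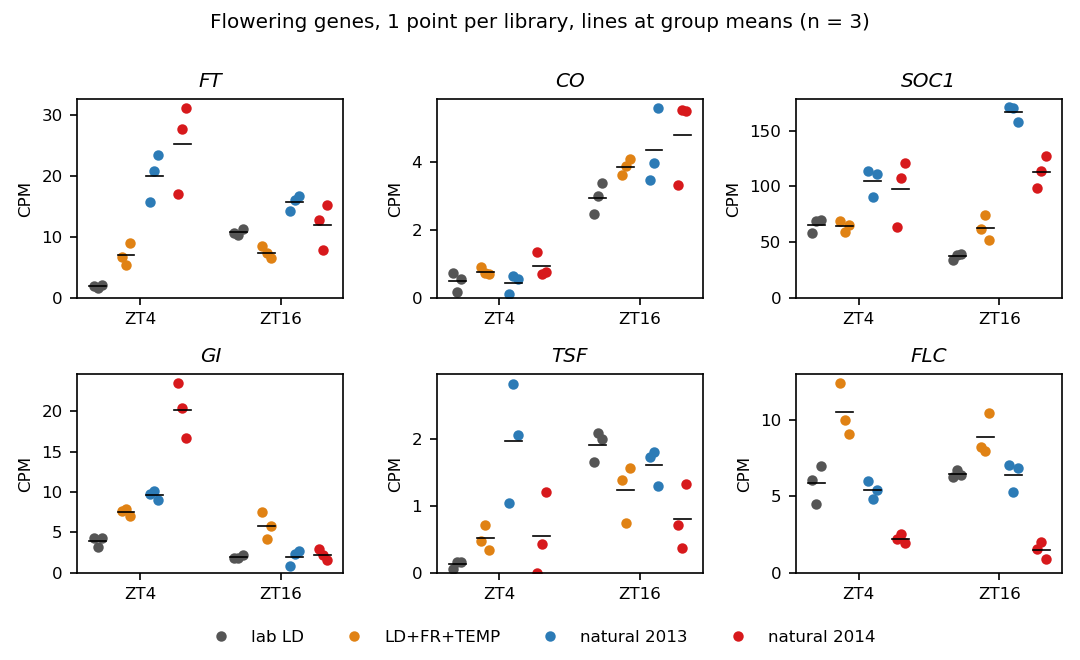
CPM (linear axis from 0) of FT, CO, SOC1, GI, TSF and FLC at ZT4 and ZT16 in lab LD, LD+FR+TEMP, natural 2013 and natural 2014, with 1 point per library and a line at each group mean (n = 3). FT at ZT4 has a mean of 1.84 CPM in lab LD and 25.2 CPM in natural 2014, whereas the group mean of CO stays at or below 0.941 CPM at ZT4 and lies between 2.94 and 4.78 CPM at ZT16.

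The first comparison asked what far-red light and a daily temperature cycle, added indoors, changed in the morning. LD+FR+TEMP at ZT4 had higher FT, higher GI (AT1G22770), a clock component that promotes flowering (0.92 ± 0.22), and higher FLC (AT5G10140), a repressor of flowering (0.84 ± 0.17). It had lower TEM1 and TEM2, repressors of FT (-1.44 ± 0.38 and -1.5 ± 0.36), although TEM1 did not pass without lab LD ZT4 replicate 1 (-1.14). CO (AT5G15840), the photoperiod activator of FT, did not pass (0.59 ± 0.43), nor did TSF (1.98 ± 0.74), the closest relative of FT, SOC1 (-0.03 ± 0.16), FKF1 (-0.26 ± 0.16) or CDF1 (0.21 ± 0.13). TSF passed when natural 2014 ZT4 replicate 1 was left out of the fit (1.98). Of 14 flowering promoters 2 rose and 2 fell, with 3 and 2 adjusted over the list alone, and of 18 repressors 1 rose and 2 fell, with 1 and 2 adjusted over the list alone.

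In LD+FR+TEMP at ZT4, HFR1 (AT1G02340) and PIL1, which react quickly to a low red to far-red ratio, rose by 2.33 ± 0.26 and 2.1 ± 0.27, and so did ATHB2 (0.97 ± 0.19). PIF4 (AT2G43010), a growth-promoting transcription factor, fell by 0.50 ± 0.12. In all, 3 of 20 shade avoidance genes rose and 7 fell, as also adjusted over the list alone. The list as a whole did not pass (adjusted p = 0.886), with a median of -0.03 and a mean of 0.06. Flavonoid and anthocyanin genes rose in 10 of 19 cases and fell in 0, with 11 and 0 adjusted over the list alone, and a median of 1.06 (camera adjusted p = 1.51e-21, adjusted p = 0.0137 with an estimated correlation). Among them F3H (AT3G51240) rose by 2.36 ± 0.14, FLS1 by 1.93 ± 0.14 and CHIL by 1.60 ± 0.13. UV-B and high light genes rose in 10 of 16 cases and fell in 0, with 11 and 0 adjusted over the list alone (adjusted p = 1.27e-11, adjusted p = 0.00849 with an estimated correlation), led by ELIP1 (AT3G22840) and ELIP2, which protect chloroplasts in strong light, at 3.55 ± 0.29 and 3.42 ± 0.24.

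Genes induced by sugar starvation and darkness fell in 8 of 9 cases and rose in 0, likewise adjusted over the list alone, with a median of -1.26 (adjusted p = 1.22e-14, adjusted p = 0.00144 with an estimated correlation). DIN10 (AT5G20250) stood at -2.24 ± 0.23, TPS11 at -1.66 ± 0.19 and TPS8 at -1.24 ± 0.18. Senescence genes fell in 4 of 7 cases and rose in 0, likewise adjusted over the list alone (adjusted p = 0.000149, adjusted p = 0.012 with an estimated correlation), among them NAP (-2.67 ± 0.24) and ORE1 (-1.52 ± 0.36), regulators of leaf ageing. Photosynthesis genes fell in 9 of 20 cases and rose in 0, with 9 and 1 adjusted over the list alone (adjusted p = 0.000914, adjusted p = 0.332 with an estimated correlation). Abscisic acid and drought genes fell in 7 of 16 cases, 8 adjusted over the list alone (adjusted p = 0.000938, adjusted p = 0.332 with an estimated correlation), with NAC019 at -4.53 ± 0.75. Iron deficiency genes rose in 4 of 14 cases, 5 adjusted over the list alone (adjusted p = 0.00149, adjusted p = 0.226 with an estimated correlation), with the iron transporter gene OPT3 at 1.59 ± 0.21. Root markers, which follow the share of root in the seedling, rose in 2 of 13 cases, 3 adjusted over the list alone (adjusted p = 0.00738, adjusted p = 0.255 with an estimated correlation). Aliphatic glucosinolate genes rose in 7 of 16 cases, 9 adjusted over the list alone (adjusted p = 0.00157, adjusted p = 0.332 with an estimated correlation). Auxin response genes fell in 4 of 15 cases, 5 adjusted over the list alone (adjusted p = 0.033, adjusted p = 0.332 with an estimated correlation). Gibberellin genes rose in 2 of 9 cases and fell in 2, with 2 and 3 adjusted over the list alone. GA3OX2, which makes active gibberellin, stood at 2.21 ± 0.27. No heat shock gene of 15 passed, 0 adjusted over the list alone. Of the seed storage markers 2 were tested and both rose, too few for a test of the list. In total 1567 genes were higher and 1617 lower in LD+FR+TEMP at ZT4, of which 198 and 519 by at least 2-fold. With only the groups compared the total was 1838 beside 3184, and 1778 of the 3111 called genes also tested there (57.2%) kept their call.

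In the evening the same indoor comparison gave fewer genes. GI rose by 1.59 ± 0.24 and SOC1 (AT2G45660), an integrator of flowering signals, by 0.76 ± 0.16. CDF3 and CDF2, repressors of CO and FT, rose by 1.33 ± 0.19 and 0.82 ± 0.19. CO (0.39 ± 0.25), TSF (-0.64 ± 0.39) and FLC (0.45 ± 0.17) did not pass. HFR1 rose by 2.31 ± 0.34 and PIF4 by 1.55 ± 0.17, 2 of 4 shade avoidance genes of 20 that rose, 5 adjusted over the list alone, with 0 that fell (adjusted p = 3.81e-05, adjusted p = 0.0301 with an estimated correlation). Root markers rose in 5 of 13 cases, 9 adjusted over the list alone (adjusted p = 4.24e-07, adjusted p = 0.0301 with an estimated correlation), led by the vacuolar water channel gene TIP2;3 (2.07 ± 0.34). Cell division genes rose in 2 of 11 cases, 6 adjusted over the list alone (adjusted p = 3.06e-05, adjusted p = 0.0301 with an estimated correlation), with KNOLLE at 0.42 ± 0.10. Photosynthesis genes rose in 7 of 20 cases, likewise adjusted over the list alone (adjusted p = 1.28e-06, adjusted p = 0.163 with an estimated correlation). Flavonoid genes fell in 4 of 19 cases, 9 adjusted over the list alone (adjusted p = 1.28e-06, adjusted p = 0.205 with an estimated correlation), with MYB75, an activator of anthocyanin synthesis, at -1.31 ± 0.31. Several of these calls were lost under other settings. SOC1 did not pass without LD+FR+TEMP ZT16 replicate 2 (0.60) or lab LD ZT16 replicate 1 (0.68). CDF2 did not pass without LD+FR+TEMP ZT16 replicate 1 (0.78) or 2 (0.73) or lab LD ZT16 replicate 1 (0.62) or 3 (0.84). KNOLLE did not pass without LD+FR+TEMP ZT16 replicate 1 (0.40) or lab LD ZT16 replicate 1 (0.40), 2 (0.45) or 3 (0.41), or with libraries thinned to the smallest (0.37). MYB75 did not pass without LD+FR+TEMP ZT16 replicate 1 (-1.4) or 2 (-1.15) or lab LD ZT16 replicate 1 (-1.17) or 2 (-1.16), with limma-trend (-1.09) or with thinned libraries (-1.19). In total 311 genes were higher and 188 lower. This count of 499 was unstable when single libraries were left out. It was 151, 94 and 1209 without LD+FR+TEMP ZT16 replicate 1, 2 and 3, and 66, 197 and 253 without lab LD ZT16 replicate 1, 2 and 3. Each such fit also had a smaller group, which can lower a count by itself. The count rose only without LD+FR+TEMP ZT16 replicate 3. With all libraries, the count was 308 with limma-trend and 285 with thinned libraries.

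Natural LD was then compared with lab LD, which asks how the outdoor seedling differs from the laboratory one. At ZT4, FT was joined by GI (1.81 ± 0.19), SOC1 (0.63 ± 0.14) and AGL24 (0.69 ± 0.16), a partner of SOC1, whereas CDF1 (-0.38 ± 0.12) and FLC (-0.75 ± 0.18) fell. With 2013 alone neither CDF1 (-0.2) nor FLC (-0.11) passed, and FLC stood at -1.38 with 2014 alone. FLC also did not pass with thinned libraries (-0.53), nor CDF1 without lab LD ZT4 replicate 2 (-0.33). TSF rose by 2.99 ± 0.67 at means no higher than 1.97 ± 0.893 CPM. CO (0.29 ± 0.44) and FKF1 (-0.34 ± 0.15) did not pass, although FKF1 did with limma-trend (-0.31), a mean of at least 5 CPM (-0.38) and thinned libraries (-0.43). Flowering promoters rose in 8 of 14 cases and fell in 0, with 8 and 1 adjusted over the list alone (adjusted p = 0.00237, adjusted p = 0.107 with an estimated correlation). Floral organ markers rose in 5 of 6 cases, likewise adjusted over the list alone (adjusted p = 0.00493, adjusted p = 0.171 with an estimated correlation), with SEP3 at 2.57 ± 0.37 and SEP1 at 3.18 ± 0.46. These markers were listed to follow the share of floral tissue, which was not measured, and they moved in the same direction as the promoters. Morning clock genes rose in 8 of 13 cases and fell in 1, likewise adjusted over the list alone (adjusted p = 3.49e-05, adjusted p = 0.0762 with an estimated correlation), with LHY (AT1G01060) at 1.98 ± 0.17 and CCA1 (AT2G46830) at 1.12 ± 0.10, the paired morning repressors of the clock.

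Stress and light genes were compared in the same way. Heat shock genes rose in 14 of 15 cases, likewise adjusted over the list alone, with a median of 3.94 (adjusted p = 4.68e-09, adjusted p = 0.171 with an estimated correlation), among them the chaperone gene HSP90.1 (AT5G52640) at 4.86 ± 0.55. The list differed between the years by a median of 7.16 at ZT4, so this mean of both rested mainly on 2014. HSP90.1 stood at 8.5 with 2014 alone and did not pass with 2013 alone (1.23), with 3.00 ± 0.496 CPM in lab LD, 7.08 ± 3.93 CPM in natural 2013 and 1100.0 ± 1020.0 CPM in natural 2014. Genes of UV-B and high light rose in 15 of 16 cases, likewise adjusted over the list alone, with a median of 1.80 (adjusted p = 6.75e-24, adjusted p = 0.000327 with an estimated correlation), with HY5 (AT5G11260), a central regulator of light responses, at 1.88 ± 0.13 and HYH, its relative, at 2.74 ± 0.14. HY5 stood at 0.80 with 2013 alone and at 2.96 with 2014 alone. The flavonoid list divided into 12 that rose and 6 that fell of 19, likewise adjusted over the list alone (adjusted p = 0.000336, adjusted p = 0.395 with an estimated correlation). Among those that rose were F3H at 2.39 ± 0.14 and FLS1 at 1.78 ± 0.13, and at 1.2 and 0.84 in 2013 alone and 3.58 and 2.72 in 2014 alone. Among those that fell were DFR at -2.53 ± 0.30, LDOX at -2.63 ± 0.31 and UGT79B1 at -2.29 ± 0.34. Auxin response genes fell in 12 of 15 cases, 13 adjusted over the list alone (adjusted p = 1.72e-07, adjusted p = 0.0208 with an estimated correlation), with IAA1 at -1.56 ± 0.14. Of the shade avoidance genes, PIF4 fell by 1.5 ± 0.11, more than in LD+FR+TEMP. HFR1 and PIL1 rose by 2.33 ± 0.24 and 2.18 ± 0.26, close to their values in LD+FR+TEMP. These genes do not stand for the whole shade avoidance list. Phosphate starvation genes rose in 9 of 11 cases, likewise adjusted over the list alone (adjusted p = 3.55e-06, adjusted p = 0.0708 with an estimated correlation), with SPX1 at 2.48 ± 0.20. Sugar starvation genes fell in 6 of 9 cases and rose in 1, with 7 and 1 adjusted over the list alone (adjusted p = 1.48e-06, adjusted p = 0.0208 with an estimated correlation). Of 62 called values named for natural LD here and in the comparisons that follow, 28 differed over 1.5 times between 2013 alone and 2014 alone, 23 of them with the larger change in 2014. In total 3714 genes were higher and 3984 lower, of which 640 and 1098 by at least 2-fold.

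The same comparison was made at ZT16. SPL3 (AT2G33810) and SPL4, targets of the age pathway of flowering, rose by 2.59 ± 0.20 and 1.71 ± 0.21, SOC1 by 1.89 ± 0.15 and CO by 0.63 ± 0.23 (adjusted p = 0.0311). CDF1 fell by 1.52 ± 0.17 and FLC by 1.06 ± 0.17. FLC stood at -0.02 with 2013 alone and at -2.09 with 2014 alone, and only the latter passed. CO did not pass with 2013 alone (0.56), with thinned libraries (0.46), without natural 2013 ZT16 replicate 3 (0.52), without natural 2014 ZT16 replicate 2 (0.57) or 3 (0.57), or without lab LD ZT16 replicate 1 (0.5) or 2 (0.64). Flowering promoters rose in 9 of 14 cases and fell in 0, with 10 and 0 adjusted over the list alone (adjusted p = 8.16e-06, adjusted p = 0.0352 with an estimated correlation). Repressors fell in 8 of 18 cases and rose in 1, with 8 and 2 adjusted over the list alone (adjusted p = 0.0297, adjusted p = 0.26 with an estimated correlation). All 6 floral organ markers rose, likewise adjusted over the list alone (adjusted p = 2.38e-05, adjusted p = 0.043 with an estimated correlation), with SEP3 at 3.93 ± 0.36. Sugar starvation genes rose in 8 of 9 cases, likewise adjusted over the list alone, with a median of 1.89 (adjusted p = 2.53e-15, adjusted p = 0.00149 with an estimated correlation), with DIN10 at 2.92 ± 0.18 and AKINBETA1, a subunit of the energy-sensing kinase, at 2.09 ± 0.16. All 19 flavonoid genes fell, likewise adjusted over the list alone (adjusted p = 2.53e-15, adjusted p = 0.043 with an estimated correlation), with MYB75 at -3.07 ± 0.32. HFR1 rose by 3.14 ± 0.31 and IAA29 by 2.42 ± 0.28. Jasmonate and ethylene defence genes fell in 10 of 16 cases and rose in 2, likewise adjusted over the list alone (adjusted p = 0.00146, adjusted p = 0.26 with an estimated correlation), with MYC2, the main regulator of jasmonate responses, at -1.47 ± 0.15. Cell division genes rose in 6 of 11 cases and fell in 1, with 7 and 1 adjusted over the list alone (adjusted p = 0.0301, adjusted p = 0.26 with an estimated correlation). In total 3576 genes were higher and 3729 lower, of which 419 and 803 by at least 2-fold.

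Natural LD against LD+FR+TEMP asked what remained different once far-red light and a temperature programme had been added indoors. That programme was not compared with the outdoor temperatures, so a remaining difference can still come from temperature. Growth site and depth also differed between these groups, and batch may have. In the morning FT, GI (0.88 ± 0.18), SOC1 (0.65 ± 0.14) and AGL24 (1.46 ± 0.18) were higher outdoors, and FLC (-1.58 ± 0.17), CDF1 (-0.59 ± 0.12) and PIF4 (-1.0 ± 0.11) were lower. With 2013 alone GI did not pass (0.35). The shade genes HFR1 (0.00 ± 0.17), PIL1 (0.08 ± 0.21) and ATHB2 (0.12 ± 0.16) did not pass. They do not stand for the whole shade avoidance list, as PIF4, also a member, was lower. HFR1 and PIL1 were looked up after their values against lab LD were seen. Of 14 cold-responsive genes 4 fell and 0 rose, with 6 and 2 adjusted over the list alone (adjusted p = 0.0152, adjusted p = 0.302 with an estimated correlation), with COR15B at -3.23 ± 0.25. Heat shock genes rose in 14 of 15 cases, likewise adjusted over the list alone, with a median of 4.41 (adjusted p = 1.47e-17, adjusted p = 0.0462 with an estimated correlation). This mean of both years rested mainly on 2014, since the list differed between the years by a median of 7.16 at ZT4. UV-B and high light genes rose in 12 of 16 cases, likewise adjusted over the list alone (adjusted p = 7.62e-13, adjusted p = 0.00845 with an estimated correlation), with HYH at 1.72 ± 0.13. Phosphate starvation genes rose in 9 of 11 cases and fell in 1, likewise adjusted over the list alone (adjusted p = 2.08e-06, adjusted p = 0.0462 with an estimated correlation). Aliphatic glucosinolate genes, which make defence compounds, fell in 14 of 16 cases, likewise adjusted over the list alone (adjusted p = 1.97e-10, adjusted p = 0.0462 with an estimated correlation), with SUR1 at -0.96 ± 0.10. Auxin response genes fell in 11 of 15 cases and rose in 1, likewise adjusted over the list alone (adjusted p = 2.80e-06, adjusted p = 0.0462 with an estimated correlation). Iron deficiency genes fell in 9 of 14 cases, likewise adjusted over the list alone (adjusted p = 0.0011, adjusted p = 0.108 with an estimated correlation). Beside them, root markers fell in 9 of 13 cases, likewise adjusted over the list alone (adjusted p = 0.0017, adjusted p = 0.0966 with an estimated correlation). All 6 floral markers rose, likewise adjusted over the list alone (adjusted p = 0.000121, adjusted p = 0.0564 with an estimated correlation). In total 2812 genes were higher and 2790 lower.

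In the evening SPL3 (2.15 ± 0.19), SOC1 (1.13 ± 0.15) and FT were higher outdoors than in LD+FR+TEMP, and GI (-1.45 ± 0.21), CDF3 (-2.02 ± 0.18), CDF1 (-1.79 ± 0.16) and FLC (-1.51 ± 0.17) were lower. FLC did not pass with 2013 alone (-0.48). Flowering promoters rose in 10 of 14 cases and fell in 1, with 10 and 2 adjusted over the list alone (adjusted p = 2.24e-05, adjusted p = 0.0402 with an estimated correlation). Repressors fell in 9 of 18 cases and rose in 2, likewise adjusted over the list alone (adjusted p = 0.000502, adjusted p = 0.0916 with an estimated correlation). Sugar starvation genes rose in 8 of 9 cases, likewise adjusted over the list alone (adjusted p = 4.76e-20, adjusted p = 0.000402 with an estimated correlation), with DIN10 at 3.35 ± 0.19. Photosynthesis genes fell in 10 of 20 cases and rose in 2, with 10 and 3 adjusted over the list alone (adjusted p = 1.05e-05, adjusted p = 0.172 with an estimated correlation). Flavonoid genes fell in 13 of 19 cases, 14 adjusted over the list alone (adjusted p = 4.79e-08, adjusted p = 0.141 with an estimated correlation). Root markers fell in 9 of 13 cases, likewise adjusted over the list alone (adjusted p = 1.05e-05, adjusted p = 0.0402 with an estimated correlation). Floral markers rose in 5 of 6 cases, likewise adjusted over the list alone (adjusted p = 1.05e-05, adjusted p = 0.0402 with an estimated correlation). In total 2716 genes were higher and 3066 lower.

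**Figure D3:**
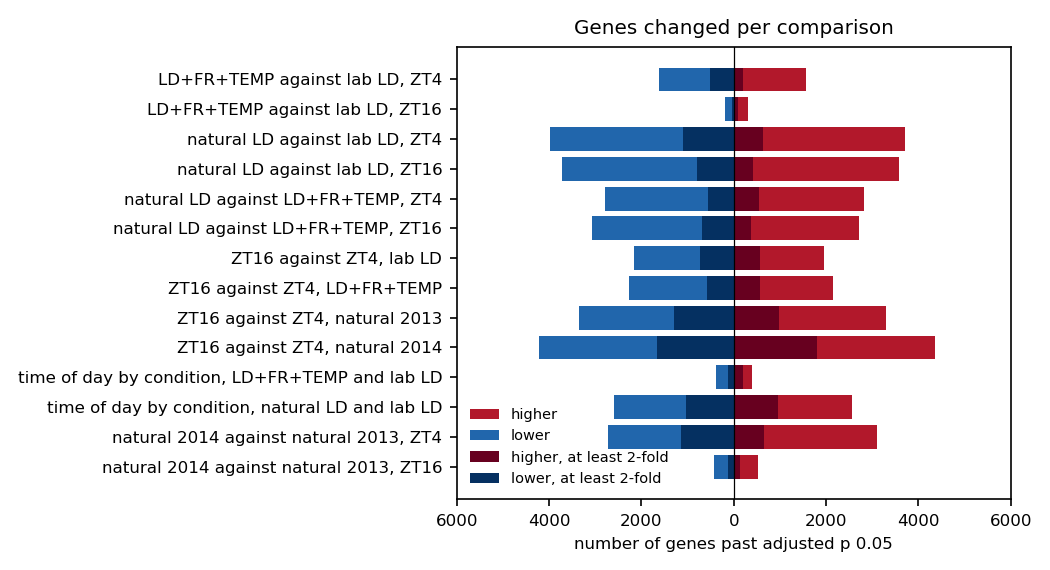
Bars give the number of genes past adjusted p 0.05 in each of 14 comparisons, higher to the right and lower to the left of 0, with the part changed by at least 2-fold darker. LD+FR+TEMP against lab LD reaches 3184 genes at ZT4 and 499 at ZT16, and natural LD against lab LD 7698 and 7305.

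How far the indoor setting moved gene expression the same way as the outdoor one was examined across genes, which are not independent replicates, from both changes against the same lab LD libraries. At ZT4 the log2 fold changes had a correlation of 0.555, beside 0.538 in 20 simulations of unchanged groups against those controls, and a covariance of 0.227 beside 0.0279, a difference of 0.199. The sign was the same in 70.5% of genes beside 68.6% in the simulations. At ZT16 the correlation was 0.363 beside 0.538, the covariance 0.079 beside 0.0256, a difference of 0.054, and the sign the same in 66.7% beside 68.7%. In the simulations the shared controls alone set the correlation and the shared sign, whatever the size of real changes. The simulated correlation and shared sign are therefore no benchmark for likeness. Of 1567 genes higher in LD+FR+TEMP at ZT4, 1052 were also higher in natural LD, where independent lists would share 310, and 47 were lower. Of 1617 lower genes 1133 were shared, where independent lists would share 343, and 49 were higher in natural LD. At ZT16 the shared genes were 172 of 311 higher, where independent lists would share 59, and 143 of 188 lower, where independent lists would share 37. The opposite direction passed in natural LD for 46 of the 311 and 8 of the 188. The few lab LD libraries at each time were not divided between the comparisons. Part of the excess of shared calls comes from the shared controls, to an extent that was not measured. In the covariance the simulated controls gave 0.0279 of 0.227 at ZT4 and 0.0256 of 0.079 at ZT16. The simulations gave all groups the same spread at a given mean. Correlations between real lab LD replicates were lower at ZT4 (0.9748 to 0.9765) than at ZT16 (0.9888 to 0.9899). The part from shared controls may therefore be larger at ZT4 than simulated.

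The time-of-day comparisons asked which genes differed between evening and morning in each setting. Clock genes marked the time in all 4 settings. Of 13 morning clock genes, 12 fell and 1, RVE2, rose from ZT4 to ZT16 in lab LD, in LD+FR+TEMP and in both outdoor years, likewise adjusted over the list alone, with the estimated correlation at an adjusted p = 2.94e-06 or below. CCA1 stood at -5.83 ± 0.15 in lab LD, -6.15 ± 0.15 in LD+FR+TEMP, -7.77 ± 0.18 in natural 2013 and -7.88 ± 0.18 in natural 2014. Afternoon and evening clock genes rose in 8, 8, 6 and 7 of 11 cases in these settings and fell in 2, 0, 2 and 3, with 8, 8, 6 and 8 and 2, 1, 3 and 3 adjusted over the list alone. TOC1 (AT5G61380) rose by 2.55 ± 0.15, 3.01 ± 0.15, 2.97 ± 0.17 and 3.96 ± 0.18. CO rose by 2.52 ± 0.34, 2.31 ± 0.31, 3.36 ± 0.41 and 2.35 ± 0.36, FKF1 by 1.09 ± 0.14, 1.58 ± 0.14, 1.31 ± 0.17 and 1.46 ± 0.17. CDF1 stood at -2.63 ± 0.15, -2.57 ± 0.15, -3.91 ± 0.20 and -3.64 ± 0.19.

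FT rose 5.80-fold from morning to evening in lab LD (2.54 ± 0.26, adjusted p = 2.96e-08), stood at 0.08 ± 0.22 in LD+FR+TEMP (adjusted p = 0.836) and at -0.35 ± 0.21 in natural 2013 (adjusted p = 0.211), and fell by 1.09 ± 0.21 in natural 2014 (adjusted p = 0.000114). TSF rose by 3.86 ± 0.60 in lab LD and did not pass in the other settings. The difference from lab LD passed for natural LD (-3.74 ± 0.76) and not for LD+FR+TEMP (-2.62 ± 0.84). For LD+FR+TEMP it passed with only the groups compared (-2.65) and without natural 2014 ZT4 replicate 1 in the fit (-2.64). Photosynthesis genes fell in 17, 14, 15 and 14 of 20 cases in lab LD, LD+FR+TEMP, natural 2013 and natural 2014, with 18, 16, 15 and 14 adjusted over the list alone, all past the threshold with an estimated correlation. UV-B and high light genes fell in 9, 12, 13 and 14 of 16 cases, with 11, 13, 13 and 14 adjusted over the list alone, also past it with an estimated correlation. Their medians were -1.23, -2.03, -3.38 and -4.52, the first and the second -1.06 and -1.83 with APX2, at 0 counts in the evening, set to a bound. Auxin response genes fell in 13, 14, 11 and 8 of 15 cases, with 14, 14, 11 and 8 adjusted over the list alone. The auxin list passed with an estimated correlation indoors (adjusted p = 4.24e-05 and adjusted p = 0.000432) and not in natural 2013 (adjusted p = 8.25e-05, adjusted p = 0.0506 with an estimated correlation). In natural 2014 it did not pass at all (adjusted p = 0.103). Sugar starvation genes fell in 7 of 9 cases and rose in 1 in lab LD, likewise adjusted over the list alone (adjusted p = 5.24e-07, adjusted p = 0.00986 with an estimated correlation). In natural 2013 they rose in 6 cases and fell in 1, likewise adjusted over the list alone (adjusted p = 0.00122, adjusted p = 0.0957 with an estimated correlation). In natural 2014 they rose in 7 and fell in 1, with 7 and 2 adjusted over the list alone (adjusted p = 1.43e-07, adjusted p = 0.0158 with an estimated correlation). The morning to evening counts were 1951 higher and 2169 lower genes in lab LD, 2151 and 2269 in LD+FR+TEMP, 3309 and 3355 in natural 2013, and 4355 and 4227 in natural 2014.

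**Figure D4:**
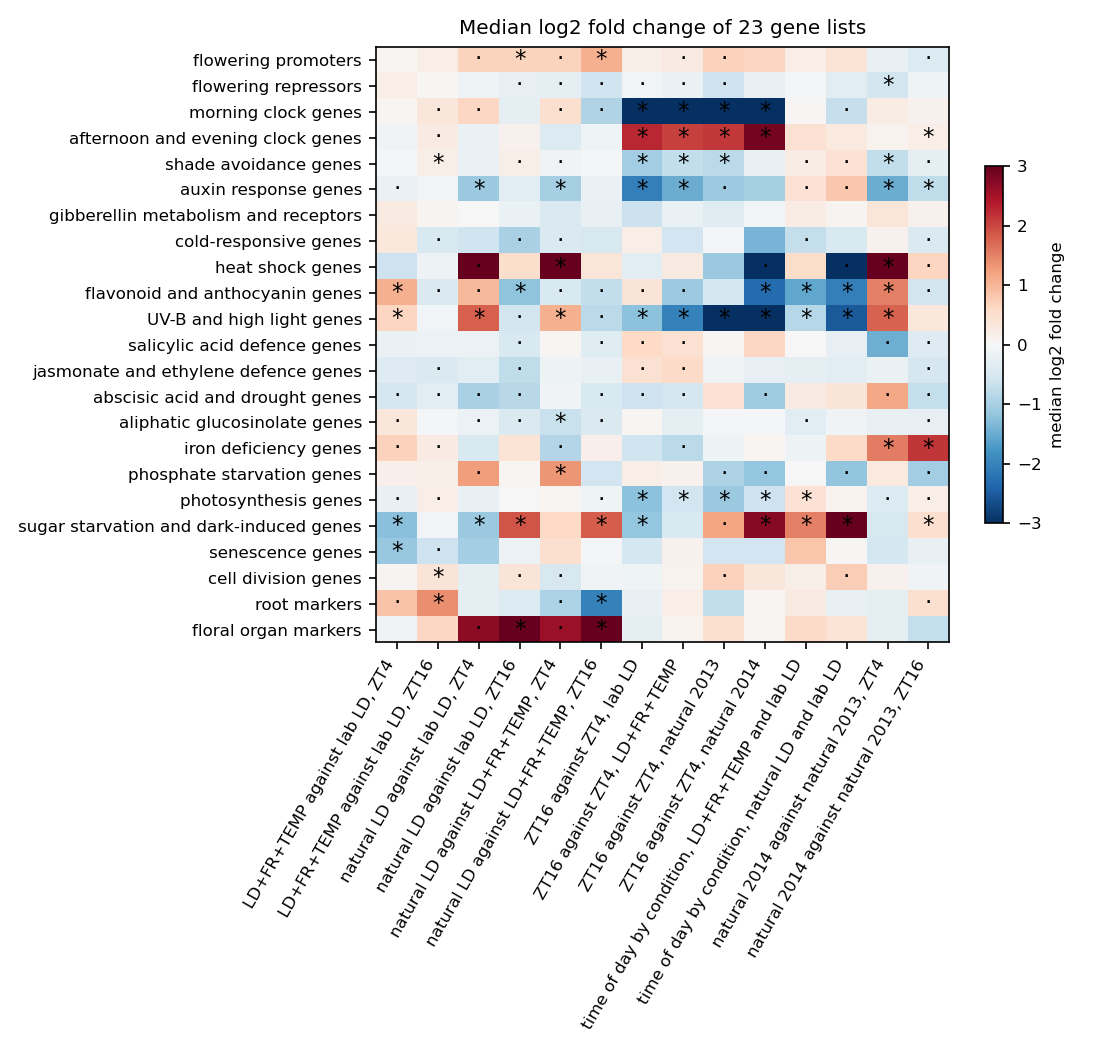
Colours give the median log2 fold change of 23 gene lists in 14 comparisons, on a scale that ends at -3 and 3. A star marks a list past adjusted p 0.05 with both the preset and an estimated correlation and a dot 1 past it with the preset alone. Morning clock genes fall in all 4 comparisons of ZT16 with ZT4, while sugar starvation genes change sign between lab LD and natural LD.

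The interaction of time and condition tested whether the condition effect at ZT16 differed from that at ZT4. For FT it was -2.45 ± 0.35 in LD+FR+TEMP (adjusted p = 0.000119) and -3.26 ± 0.30 in natural LD (adjusted p = 5.51e-09), each against lab LD. With LD+FR+TEMP, PIF4 (2.05 ± 0.21) and LNK1 (1.36 ± 0.17), a clock coactivator, had a higher evening effect, and F3H (-2.68 ± 0.20) and ELIP2 (-2.60 ± 0.42) a lower one. Flavonoid genes were lower in 12 of 19 cases, 15 adjusted over the list alone (median -1.55, adjusted p = 2.56e-40, adjusted p = 0.00199 with an estimated correlation). UV-B and high light genes were lower in 8 of 16, 11 adjusted over the list alone (median -0.85, adjusted p = 3.40e-13, adjusted p = 0.0029 with an estimated correlation). Sugar starvation genes were higher in 7 of 9 cases, 8 adjusted over the list alone (median 1.5, adjusted p = 3.12e-12, adjusted p = 0.00199 with an estimated correlation). Photosynthesis genes were higher in 8 of 20, 11 adjusted over the list alone (median 0.43, adjusted p = 2.72e-12, adjusted p = 0.0406 with an estimated correlation). This interaction passed for 405 higher and 392 lower genes, 797 in all, and for 508 without LD+FR+TEMP ZT4 replicate 2 and 501 without lab LD ZT16 replicate 1.

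With natural LD, TPS11 (4.59 ± 0.26), IAA29 (4.57 ± 0.38) and PIF4 (2.27 ± 0.20) had a higher evening effect, and LHY (-3.88 ± 0.30), LUX (-2.13 ± 0.15) and GI (-1.67 ± 0.32) a lower one. SOC1 was higher (1.26 ± 0.20), as were SPL3 and SPL4 (1.86 ± 0.29 and 2.07 ± 0.31), and CO did not pass (0.34 ± 0.50). Sugar starvation genes were higher in 8 of 9 cases and lower in 1, likewise adjusted over the list alone (median 4.03, adjusted p = 7.83e-24, adjusted p = 8.03e-05 with an estimated correlation). Genes of UV-B and high light were lower in 13 of 16 cases, likewise adjusted over the list alone (median -2.52, adjusted p = 6.81e-23, adjusted p = 0.000153 with an estimated correlation). Flavonoid genes were lower in 14 of 19 cases and higher in 1, with 15 and 3 adjusted over the list alone (median -2.04, adjusted p = 1.35e-19, adjusted p = 0.0271 with an estimated correlation). Heat shock genes were lower in 9 of 15 cases, 10 adjusted over the list alone (adjusted p = 6.19e-07, adjusted p = 0.237 with an estimated correlation). Cell division genes were higher in 7 of 11 cases, likewise adjusted over the list alone (adjusted p = 0.00526, adjusted p = 0.124 with an estimated correlation). No root marker of 13 passed. The interaction passed for 2556 higher and 2604 lower genes, 5160 in all, and for 3272 with 2013 alone.

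The comparison of the outdoor years asked how far a natural long day differed from another. At ZT4 all 15 heat shock genes were higher in 2014, likewise adjusted over the list alone, with a median of 7.16 (adjusted p = 2.17e-21, adjusted p = 0.0273 with an estimated correlation). HSFA2 (AT2G26150), a regulator of the heat shock response, stood at 8.38 ± 0.46, HSP90.1 at 7.26 ± 0.57 and MBF1C, a coactivator of that response, at 5.70 ± 0.33. UV-B and high light genes rose in 15 of 16 cases, likewise adjusted over the list alone (adjusted p = 3.89e-25, adjusted p = 0.000371 with an estimated correlation). Flavonoid genes rose in 13 of 19 cases, likewise adjusted over the list alone (adjusted p = 2.71e-16, adjusted p = 0.0273 with an estimated correlation). Shade avoidance genes fell in 12 of 20 cases and rose in 0, with 12 and 1 adjusted over the list alone (adjusted p = 5.00e-07, adjusted p = 0.00981 with an estimated correlation). Auxin response genes fell in 11 of 15 cases, likewise adjusted over the list alone (adjusted p = 2.25e-07, adjusted p = 0.0184 with an estimated correlation). Flowering repressors fell in 8 of 18 cases, 12 adjusted over the list alone (adjusted p = 5.03e-05, adjusted p = 0.0273 with an estimated correlation), among them TEM1 (-4.08 ± 0.57), CDF3 (-1.10 ± 0.15) and FLC (-1.27 ± 0.25). FT did not differ past the threshold (0.34 ± 0.21, adjusted p = 0.217), but passed without natural 2014 ZT4 replicate 1 (0.55). In total 3110 genes were higher in 2014 and 2724 lower, of which 646 and 1140 by at least 2-fold.

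At ZT16 the years differed less. Iron deficiency genes were higher in 2014 in 10 of 14 cases, 13 adjusted over the list alone, with a median of 2.14 (adjusted p = 5.43e-21, adjusted p = 0.000517 with an estimated correlation). The iron reductase gene FRO2 stood at 2.57 ± 0.42. Sugar starvation genes were higher in 5 of 9 cases, likewise adjusted over the list alone (adjusted p = 5.45e-09, adjusted p = 0.00616 with an estimated correlation). Auxin response genes were lower in 4 of 15 cases, 9 adjusted over the list alone (adjusted p = 3.09e-09, adjusted p = 0.00616 with an estimated correlation). Salicylic acid defence genes fell in 5 of 15 cases, 7 adjusted over the list alone (adjusted p = 4.34e-07, adjusted p = 0.0757 with an estimated correlation), with PR2 at -4.99 ± 0.66. FLC fell by 2.07 ± 0.24, and FT did not differ past the threshold (-0.40 ± 0.22, adjusted p = 0.326). In total 531 genes were higher and 438 lower, 969 in all. That count was 523, 339 and 594 without natural 2013 ZT16 replicate 1, 2 and 3, and 551 and 423 without natural 2014 ZT16 replicate 1 and 2. It was 1485 with only the groups compared.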

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

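The test of the morning clock genes for exchanged libraries, the test of the root markers, the test of year by time, the thinned libraries and the dropped library were chosen after results had been seen. Groups of 3 libraries were not tested for single far-off samples. The interactions below stood out because the effect of 1 factor differed between groups in a test of the difference itself. The patterns weighed after them also include a contrast of the outdoor years and a comparison of counts. The difference of those counts was not tested.

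The effect of time of day differed between LD+FR+TEMP and lab LD in 797 genes, and the FT interaction was -2.45. The median interaction was -1.55 in flavonoid genes, -0.85 in UV-B and high light genes, 0.43 in photosynthesis genes and 1.5 in sugar starvation genes. In 6 of 100 splits of the same libraries, the real one included, as many genes passed, with 3459 in the highest other split. Libraries were split at each time separately, so a split could keep the condition effect of 1 time and lose the other. Such splits do not represent an absent interaction. Their share therefore cannot decide on chance for the count, and chance is not excluded. That highest split exchanged the 3 LD+FR+TEMP libraries with the 3 lab LD libraries at 1 time and 0 at the other. It thereby summed the condition effects of both times, which is a structure of the samples.

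Between natural LD and lab LD, the effect of time of day differed in 5160 genes, and the FT interaction was -3.26. The median was -2.04 in flavonoid genes, -2.52 in UV-B and high light genes and 4.03 in sugar starvation genes. In 1 of 100 splits, the real one, as many genes passed, a share under 0.05, and the highest other split gave 3503. That split, too, exchanged 3 libraries at 1 time and 0 at the other. Here as well the splits do not represent an absent interaction, so the share does not decide on chance. Splits of libraries do not exclude an effect of planting, site or batch. Between the outdoor years, the effect of time of day differed in 3211 genes, 1559 higher and 1652 lower. The median of the heat shock genes was -4.48, with 8 of 15 lower (adjusted p = 2.58e-14, adjusted p = 0.0624 with an estimated correlation).

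The first pattern weighed was the heat shock genes at ZT4, higher in natural 2014 than in natural 2013 with a median of 7.16. The SE of the mean over members was 0.72, which does not measure the spread between samples. In 14 of 15 members every 2014 library lay above every 2013 library, where chance gives 5% per gene in this direction and 10% in either. The pattern was picked from these same libraries and its members are not independent, so this count adds no separate support. Of all 18797 genes tested, 3110 were higher in 2014 past the threshold, and their non-overlap was not counted. Left-out libraries gave 5.79 to 7.69 and thinning all libraries to the smallest (6543615 counts) gave 7.05, which argue against 1 unlike library and depth as the whole cause. The gene filter was run again each time, so the members tested could differ. Relative log expression factors gave 7.17. They moved the median of all genes by only 0.009, so this test could not decide on scaling. The morning clock genes had a median of -5.89 from ZT4 to ZT16 in 2014, which argues against exchanged times. The weather of the sampling days and the sampling batch remain open and untested, and a warmer morning in 2014 is a candidate explanation.

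The second pattern was the sugar starvation genes, whose interaction of time with natural LD had a median of 4.03. The SE of the mean over members was 0.66, which does not measure the spread between samples. Thinning gave 3.9 and left-out libraries 2.99 to 3.93, which argue against depth and 1 unlike library as the whole cause. The gene filter was run again each time, so the members tested could differ, and all left-out values lay below 4.03. Relative log expression factors gave 4.01. They moved the median of all genes by only -0.02, so this test could not decide on scaling. The root markers had a median of -0.22, which argues against a changed share of root. A difference in carbon supply or in light before ZT16 outdoors may contribute, and was not tested.

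The third pattern was the larger count of genes at ZT16 for natural LD (7305) than for LD+FR+TEMP (499), each against lab LD. With thinned libraries the counts were 6181 and 285, and the smaller of the outdoor years alone gave 5470, which argue against depth and against the larger number of outdoor libraries. Left-out libraries gave at least 5479 for natural LD and at most 1209 for LD+FR+TEMP, closer than the 5-fold bound set beforehand, so that bound was not met. The 5479 came without lab LD ZT16 replicate 1, where LD+FR+TEMP gave 66, and the 1209 without LD+FR+TEMP ZT16 replicate 3. No single left-out library gave both, which argues against 1 unlike library as the whole cause of the larger count. Its share cannot be told apart here. The growth site and its batch are confounded with these groups and stay open.

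The other counts were set beside splits of the same libraries. With 10 splits each, too few for a share under 0.05, the real and the highest other count were 3184 and 3 for LD+FR+TEMP against lab LD at ZT4, 499 and 1 at ZT16, 4120 and 6 for ZT16 against ZT4 in lab LD, 4420 and 0 in LD+FR+TEMP, 6664 and 0 in natural 2013, 8582 and 0 in natural 2014, and 5834 and 1 for the outdoor years at ZT4 and 969 and 0 at ZT16. With 100 splits, only 1, the real one, gave as many for natural LD against lab LD (7698 and 6735 at ZT4, 7305 and 6820 at ZT16) and against LD+FR+TEMP (5602 and 4788, 5782 and 5404), a share under 0.05. Those highest splits kept structure of the samples. At ZT16 0 libraries changed side, so outdoor libraries were only exchanged between the years, and at ZT4 3 changed side. The median of the other splits was 0 genes. Because splits treat libraries as independent, they do not exclude an effect of planting, site or batch.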

How the results depend on the processing

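Thinned libraries and the drop of natural 2014 ZT4 replicate 1 were chosen after seeing the data. Of 278 alternatives for the 14 counts of genes, 246 stayed within 1.5 times the count, 30 gave fewer and 2 more. With a log2 fold change of at least 1, which passes fewer genes by construction, the counts were 717 and 132 for LD+FR+TEMP against lab LD at ZT4 and ZT16, 1738 and 1222 for natural LD against lab LD, 1092 and 1071 for natural LD against LD+FR+TEMP, 1296, 1135, 2276 and 3456 for ZT16 against ZT4 in lab LD, LD+FR+TEMP, natural 2013 and natural 2014, 309 and 1994 for the interactions with LD+FR+TEMP and natural LD, and 1786 and 259 for the years.

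With only the groups compared, LD+FR+TEMP against lab LD at ZT4 gave 1838 genes and the years at ZT16 gave 1485. At ZT16, LD+FR+TEMP against lab LD gave 308 with limma-trend on the deposited values and 285 with thinned libraries. With 2013 alone the natural LD interaction gave 3272. With a mean of at least 5 CPM, LD+FR+TEMP against lab LD at ZT16 gave 455 genes, 51.9% of them higher beside 62.3%. The cause was not tested. Apart from 1 outdoor year alone, where this was not measured, no setting moved the median of all genes by over 0.1.

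With each library left out in turn, LD+FR+TEMP against lab LD gave 66 to 1209 genes at ZT16. It gave 151, 94 and 1209 without LD+FR+TEMP ZT16 replicate 1, 2 and 3, and 66, 197 and 253 without lab LD ZT16 replicate 1, 2 and 3. The LD+FR+TEMP interaction gave 501 (without lab LD ZT16 replicate 1) to 1023, and 508 without LD+FR+TEMP ZT4 replicate 2. The years at ZT16 gave 339 to 849, with 523, 339 and 594 without natural 2013 ZT16 replicate 1, 2 and 3, and 551 and 423 without natural 2014 ZT16 replicate 1 and 2. In the other comparisons each count stayed within 1.5 times.

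Of 184 alternatives for FT, 182 kept its side of the threshold. These were relative log expression factors, DESeq2, limma-trend, the replicate block, thinned libraries and left-out libraries. The other alternatives, among them only the groups compared and 1 outdoor year alone, were not examined for FT. FT for ZT16 against ZT4 in LD+FR+TEMP, which did not pass (0.08), took the other sign without LD+FR+TEMP ZT4 replicate 2 (-0.08) and without LD+FR+TEMP ZT16 replicate 1 (-0.02). FT in natural LD against lab LD at ZT16 ran from 0.24 to 0.46 over left-out libraries and passed without natural 2014 ZT16 replicate 2. Between the years at ZT4 it ran from 0.16 to 0.55 and passed without natural 2014 ZT4 replicate 1. Of 2691 alternatives for the other genes named with values (141 results), 2652 kept their side, 33 lost the threshold and 6 passed it. The sign changed in 9, among them CO in natural LD against lab LD at ZT4 (0.29, and -0.28 with 2013 alone), and in none of these did the value pass before or after (0 cases). The correlation of the LD+FR+TEMP and natural LD changes was 0.507 and 0.301 at ZT4 and ZT16 with 2013 alone, 0.483 at ZT4 with 2014 alone, and 0.655 and 0.463 over genes called in natural LD.

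Of 322 list tests 161 passed with the preset correlation, 65 with an estimated one and 184 with fry, 152 of them in both, and none of those that passed changed direction (0 tests). With a replicate block 162 passed, 160 of them in both, and no count of genes moved by over 1.5 times. Libraries with the same number had a mean correlation of deviations of -0.01 (-0.244 to 0.21), above 0.1 in 5 of 84 pairs, and 3 of 24 libraries correlated best with their own number, so the numbers were not taken as pairs. Depth limits the number of genes called, as thinning lowered all 14 counts.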

Other observations

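The interaction of year and time of day, tested after the other results had been seen, gave list values beyond the heat shock genes. Between natural 2013 and natural 2014 the change from ZT4 to ZT16 was lower in 2014 for 12 of 19 flavonoid genes (median -1.89, edgeR and camera adjusted p = 3.07e-23, adjusted p = 0.0173 with an estimated correlation), and for 9 of 16 UV-B and high light genes (median -1.46, adjusted p = 8.91e-10, adjusted p = 0.0173 with an estimated correlation). It was higher for 6 of 9 sugar starvation genes (median 1.46, adjusted p = 1.66e-06, adjusted p = 0.0289 with an estimated correlation). A further 7 lists passed with the preset correlation and not with an estimated one. Besides the heat shock genes, these were abscisic acid and drought genes, lower in 9 of 16 cases (median -1.5, adjusted p = 5.17e-09, adjusted p = 0.0531 with an estimated correlation), phosphate starvation genes, lower in 5 of 11 (median -1.33, adjusted p = 0.000882, adjusted p = 0.162), and cold-responsive genes, lower in 4 of 14 and higher in 2 (median -0.56, adjusted p = 0.000882, adjusted p = 0.199). The other 3 moved up. Photosynthesis genes were higher in 13 of 20 cases and lower in 2 (median 0.58, adjusted p = 1.02e-05, adjusted p = 0.162), shade avoidance genes higher in 11 of 20 and lower in 3 (median 0.73, adjusted p = 0.000728, adjusted p = 0.0531), and flowering repressors higher in 3 of 18 (median 0.43, adjusted p = 0.0103, adjusted p = 0.162).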
